A study of Mus musculus with 8 samples.

How the data were processed

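RNA was measured by sequencing of polyadenylated transcripts from CD11b and F4/80 sorted peritoneal macrophages of 8 mice, 4 young (2 to 3 months) and 4 aged (18 to 24 months), with 1 library per mouse. The labels call these biological replicates. The deposited table holds raw counts of reads per gene symbol, 1 column per library, with no normalization, and the column totals differ between libraries as raw counts do. Reads were aligned with HISAT2 (version 2.1.0) to mm10 and counted with featureCounts (version 2.0.6), per the submitters' processing notes. The annotation release, the strand setting and the handling of reads with several matches were not given in the sources used here, so counts of overlapping, antisense or near-identical genes are uncertain. The protocol in the labels describes poly-T selection, random hexamer priming and PCR, and names no step that marks strand.

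The table has 25239 gene rows, of which 6012 had no count in any library, and every row carried a gene name. Total counts were 21093736, 21812515, 22649092 and 23216595 in young replicates 1 to 4 and 26334309, 28237017, 27161064 and 22273980 in aged replicates 1 to 4. Genes with a count numbered 14713 to 15067 in the young and 15147 to 17130 in the aged libraries. Pairs of libraries were compared by a chi-square test over genes, and every pair differed by more than sampling noise, so no library appeared in the table under another name. Each was counted as 1 replicate, per the labels.

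Genes were tested with edgeR (version 4.0.16) in R 4.3.3 on the counts as deposited. Genes with low counts were removed by filterByExpr, which left 12325 genes, and library sizes were scaled by TMM factors. The quasi-likelihood F-test with robust dispersions compared aged with young libraries with no covariate, and p values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Log2 fold changes are aged over young, and their SE was taken from the fold change and the square root of F. CPM values use TMM-scaled library sizes and are given as mean ± SD of 4 libraries. Principal components were computed on log2 CPM with a prior count of 2.

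The question of gene groups was put to 45 lists of processes and cell types, written from general knowledge before the data were examined. The 38 lists with at least 5 tested members (31 processes and 7 cell types) were tested with camera in limma (version 3.58.1) on log2 CPM, with a preset inter-gene correlation of 0.01, two-sided, with adjustment over these lists. Camera with an estimated correlation, fry's directional p and an exact permutation of each list's mean over 70 assignments were run as alternatives. A list's members were counted as rising or falling from the edgeR test over all genes, and again with p values adjusted over the list alone. Marker lists were also compared by an exact two-sided permutation test of their mean log2 CPM per library, adjusted over 12 lists.

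Genes named in the text follow a rule set before the data were examined. It takes the 10 largest rises and the 10 largest falls among genes that passed, had a mean of at least 5 CPM and did not overlap between groups, leaving out Gm-numbered, clone-named and -ps symbols and antigen receptor segments. It adds up to 4 members with the smallest p of each list and 22 genes of interest whatever their result. Positions, transcript lengths and GC content came from GENCODE M21 on mm10, matched by symbol, and 98.5% of tested genes had a length.

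The scripts were first tested on simulated data, drawn for the aged over young comparison from the means, dispersions and sizes of the 8 libraries with 200 genes changed. Over 12234 tested genes, edgeR recovered 53.7% of 67 genes changed by 1.5-fold, 73.1% of 67 changed by 2-fold and 97.0% of 66 changed by 4-fold, and 5.70% of the genes called were not changed. In a simulation of 30 lists, camera called 3 of 3 raised lists and 0 of the others. Genes were drawn independently there, whereas the estimated correlation within the real lists reached 0.82. The simulation therefore does not test the preset correlation on lists whose genes vary together.

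Alternatives covered DESeq2 (version 1.42.0), limma-voom with and without sample quality weights, median-of-ratios, upper-quartile and total-count scaling, no filter, a filter of at least 1 CPM in 4 libraries, a block for the replicate number, and leaving out each library in turn. Removal of a length trend through offsets was added after the deviation of aged replicate 1 was seen. Immunoglobulin and mitochondrially encoded genes were not analysed here.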

Results

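The study compared the transcripts of peritoneal macrophages from young mice, 2 to 3 months old, with those from aged mice, 18 to 24 months old, to find pathways that differ with age; the series title names stress of the endoplasmic reticulum (ER), inflammation and infection. All mice were C57BL/6J females. Cells washed from the peritoneal cavity had been sorted for CD11b and F4/80, a pair of surface markers of macrophages, and polyadenylated RNA was sequenced from 4 young and 4 aged mice, 1 library per mouse. Total counts ran from 21093736 to 23216595 in the young libraries and from 22273980 to 28237017 in the aged libraries. Fn1, which encodes fibronectin, took the largest share of counts in each of the 8 libraries, from 2.19% to 4.47%.

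The 8 libraries separated by age along the first principal component of log2 CPM (library-scaled counts), which held 53.1% of the variance. The second component, with 16.8%, set aged replicate 1 apart from the other 7 libraries. In aged replicate 1, genes whose longest transcript was under 2313 bases lay a median of 0.30 log2 units above the other aged libraries, and genes with transcripts over 4928 bases lay a median of 0.39 below them (-0.39). Across genes, the deviation of this library had a Spearman rho of -0.70 with transcript length; genes are not independent replicates.

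**Figure D1:**
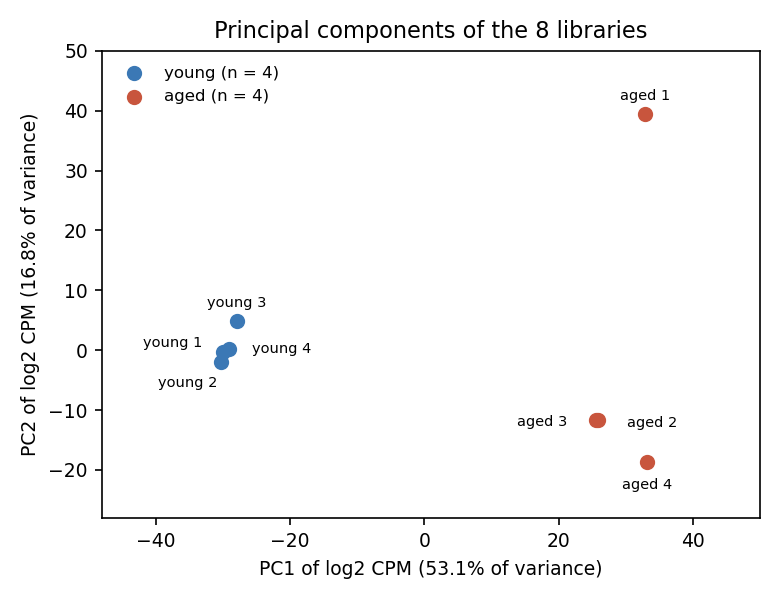
Principal components of log2 CPM of the tested genes; the x axis is PC1 (53.1% of the variance) and the y axis PC2 (16.8%), and each point is 1 library (blue, young; red, aged). The 4 young libraries lie together at the left, and aged replicate 1 lies apart from the other aged libraries along PC2.

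Of 12325 genes tested, 1703 changed with age, 1095 higher and 608 lower in aged macrophages. Of these, 467 rose and 123 fell by more than 2-fold. The hour of collection and the source of the aged mice were not given in the labels used here. A difference in either between the groups cannot be told apart from age for any gene. Among genes of at least 5 CPM whose groups did not overlap, with Gm-numbered and clone-named genes left out, the largest rises included Ifi44, an interferon-stimulated gene, with a log2 fold change of 5.28 ± 0.30 (SE, n = 4 per group) from 0.47 ± 0.30 (SD) to 18.4 ± 3.8 CPM. Pdk4, a mitochondrial kinase that restrains pyruvate oxidation, rose by 5.16 ± 0.48 on the log2 scale, and Loxl2, a lysyl oxidase acting on extracellular matrix, by 5.03 ± 0.38. Among the largest falls were Apoc1, which encodes an apolipoprotein, at -4.51 ± 0.21, the hyaluronan receptor gene Lyve1 at -3.20 ± 0.21 and the scavenger receptor gene Stab1 at -2.85 ± 0.19; Stab1 went from 800 ± 127 to 111 ± 31 CPM (SD). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 6.72e-06 for Ifi44, 3.64e-06 for Apoc1 and 8.93e-06 for Stab1. Groups of 4 did not overlap for 2560 genes (20.8% of those tested, against 2.86% by chance). The count of changed genes was 2732 without aged replicate 1 and 1107 without young replicate 1.

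The other genes of the largest rises were LOC100041034 (5.91 ± 0.42), Nexmif (4.87 ± 0.37), Gbp4 (4.67 ± 1.01), Serpina3g (4.51 ± 0.55), Cd55os (3.68 ± 0.27), Cd55 (3.64 ± 0.28) and Csprs (3.52 ± 0.26), as log2 fold change ± SE. LOC100041034 and Csprs belong to a repeated family whose copies can share reads, and Cd55os is by name the opposite-strand transcript of Cd55, with a counting strand that was not given in the sources used here, so these values are uncertain for the single genes. Gbp4 was at 78.1 CPM in aged replicate 4 and at 4.65 to 9.92 CPM in the other aged libraries, and its log2 fold change was 2.84 without aged replicate 4. Its adjusted p was 0.0116, against 0.0504 without aged replicate 1, 0.0911 with no filter on low counts and 0.134 with limma-voom (edgeR otherwise). The other large falls were Dbp (-3.50 ± 0.39), Erc2 (-2.68 ± 0.17), Per3 (-2.21 ± 0.12), Shank3 (-2.11 ± 0.27), Tef (-2.08 ± 0.16), Per2 (-1.97 ± 0.21) and Tal1 (-1.83 ± 0.28). On mm10 in GENCODE annotation, Ifi44 lies on chromosome 3 from 151730922 to 151749960, Pdk4 on chromosome 6 from 5483351 to 5496309, Apoc1 on chromosome 7 from 19689481 to 19692660 and Stab1 on chromosome 14 from 31139013 to 31168641; all are protein-coding genes.

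**Figure D2:**
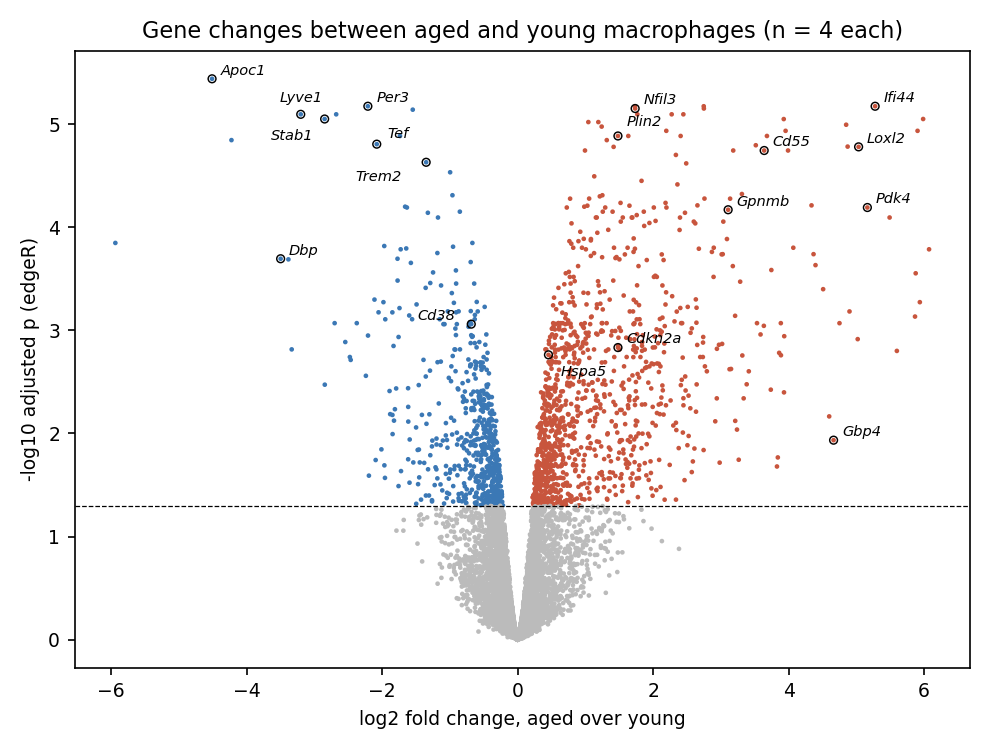
Change of each of the 12325 tested genes; the x axis is the log2 fold change, aged over young, and the y axis is −log10 of the adjusted p of edgeR (red, 1095 genes higher in aged; blue, 608 lower; grey, not passing; dashed line, adjusted p of 0.05). Ifi44, Pdk4 and Loxl2 lie far to the right, and Apoc1, Dbp, Lyve1 and Stab1 far to the left.

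The ER stress lists asked which arms of the response to unfolded protein differed with age. ER chaperones rose: of 20 tested targets of the sensor ATF6 and other chaperones, 10 rose, none fell and 10 did not pass, and 10 rose when adjusted over the list alone. Dnajc10, a disulfide reductase of the ER, rose by 0.56 ± 0.08 (log2, SE, n = 4 per group), Hsp90b1, the ER member of the HSP90 family, by 0.50 ± 0.08, the calcium-binding chaperone gene Calr by 0.52 ± 0.08 and Hspa5, the chaperone BiP, by 0.46 ± 0.07, from 685 ± 39 to 940 ± 49 CPM (SD). The mean log2 fold change of the list was 0.27, with camera adjusted p = 7.65e-06 at a preset correlation and adjusted p = 0.235 with an estimated correlation.

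None of the 23 tested targets of the sensor IRE1 and its transcription factor XBP1 passed, over all genes or adjusted over the list alone; the list's mean log2 fold change was 0.05 with camera adjusted p = 0.444, and 0.0303 and 0.0301 without young replicate 1 or aged replicate 3. Serp1 (-0.25 ± 0.08), Ssr3 (0.21 ± 0.07), Spcs3 (0.22 ± 0.07) and Hspa13 (0.24 ± 0.09) had its smallest p values, with adjusted p of 0.0578, 0.0599, 0.0620 and 0.110. All 4 passed without aged replicate 1, with adjusted p from 0.00733 to 0.0222, as they did with limma-voom and sample quality weights (0.0110 to 0.0223) and with a length trend removed (0.0196 to 0.0464). Serp1, Ssr3 and Spcs3 also passed with DESeq2, and Serp1 with total counts alone (0.0392) and without aged replicate 3 (0.0478), with log2 values of the 4 within 1.5 times those given.

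Of 28 tested targets of the kinase PERK and the factor ATF4, 4 rose, 1 fell and 23 did not pass, with 5 and 1 when adjusted over the list alone, and the list's mean of 0.26 did not pass, with camera adjusted p = 0.115. It passed without aged replicate 2 (mean 0.30, adjusted p = 0.0329), and the mean was 0.0639 over the 25 members with at least 1 CPM in 4 libraries (adjusted p = 0.389). Phgdh, an enzyme of serine synthesis, rose by 2.06 ± 0.34 and the pseudokinase gene Trib3 by 1.68 ± 0.40, both from under 1 CPM, and Ddit4, an inhibitor of mTORC1, fell by 1.48 ± 0.34 on the log2 scale (-1.48). Trib3 did not pass without young replicate 1, 2 or 4 (adjusted p of 0.0519, 0.0521 and 0.0600), nor Ddit4 without aged replicate 1 or 2 (0.0610 and 0.0505). Vldlr was counted 3 times over the 4 young libraries and 107 times over the 4 aged libraries. Of 23 genes of ER-associated degradation, 2 rose, among them Vcp (0.25 ± 0.08), 1 fell (Erlin1, -0.33 ± 0.09) and 20 did not pass; none passed when adjusted over the list alone, and camera gave adjusted p = 0.302. Vcp passed only without aged replicate 1 or 2 among the runs that left out 1 library (adjusted p up to 0.162), and so did Erlin1 (up to 0.104).

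The sensors and factors of these pathways did not pass the main test, nor did Dnajb9, a target of IRE1 and XBP1. Counts per gene give transcript levels, and the activity of these proteins was not measured here. Log2 fold changes were 0.13 ± 0.07 for Xbp1, 0.33 ± 0.16 for Ddit3, which encodes CHOP, 0.04 ± 0.12 for Atf4, -0.10 ± 0.13 for Atf6, -0.24 ± 0.22 for Ern1, which encodes IRE1, 0.18 ± 0.09 for Eif2ak3, which encodes PERK, and -0.03 ± 0.11 for Dnajb9, with adjusted p from 0.204 to 0.887 (edgeR). Eif2ak3 passed without aged replicate 1 (0.26, adjusted p = 0.00775) and with limma-voom and sample quality weights (0.27, 0.0137), and Ern1 had -0.02 without aged replicate 1 and -0.37 without aged replicate 2. Ddit3 had 0.196 without aged replicate 1 and Xbp1 0.0860 without aged replicate 3, and the signs of Atf4, Atf6 and Dnajb9 turned when 1 library was left out. Usf1, a transcription factor, had 0.23 ± 0.08 with adjusted p = 0.0856, and passed with DESeq2 (0.0447) and with a length trend removed (0.0341).

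**Figure D3:**
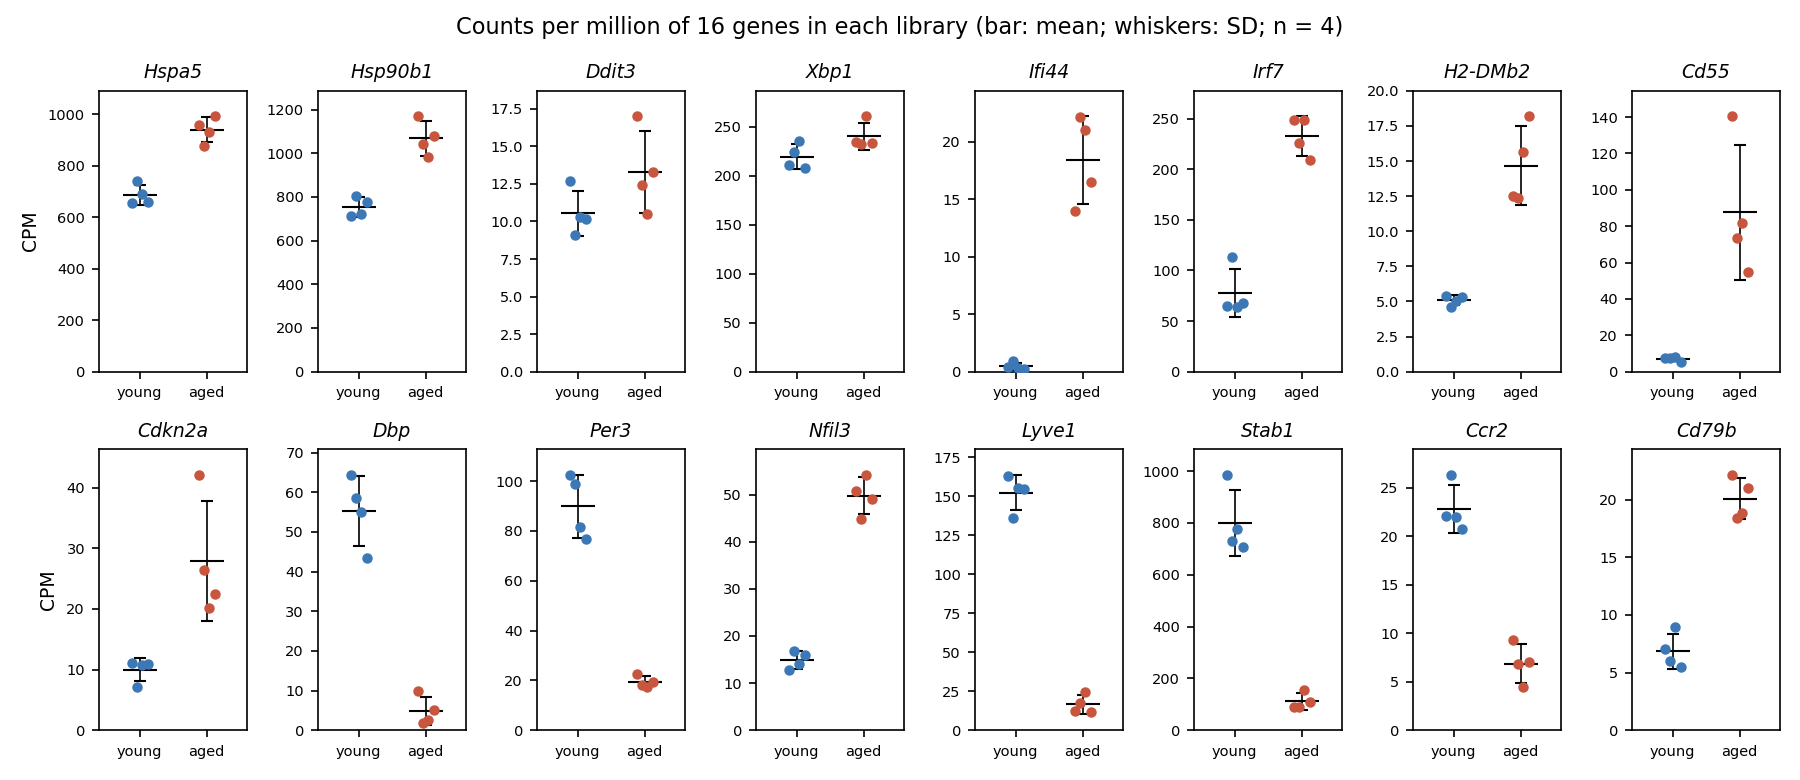
CPM of 16 genes in each of the 8 libraries (points), with the mean (bar) and SD (whiskers) of 4 libraries per group; each y axis starts at 0 and has its own scale. Hspa5 and Hsp90b1 were higher in every aged library than in any young library, while Ddit3 and Xbp1 overlapped.

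Interferon-stimulated genes rose widely in aged macrophages. Of 36 tested type I interferon-stimulated genes, 26 rose, none fell and 10 did not pass, with 32 rising when adjusted over the list alone. Irf7, a transcription factor that amplifies the interferon response, rose by 1.58 ± 0.17 (log2, SE, n = 4 per group), Cmpk2, a mitochondrial nucleotide kinase, by 1.09 ± 0.15 and Ifih1, the RNA sensor MDA5, by 0.70 ± 0.10. The list had a mean log2 fold change of 1.05 with camera adjusted p = 2.66e-17, and adjusted p = 0.267 with an estimated correlation. Young replicate 2 had the highest mean log2 CPM of this list among young libraries, 4.95 against 4.08 to 4.26 in the others, below the 5.37 to 5.45 of the aged libraries, and the mean log2 fold change was 1.25 without it.

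Of 25 genes induced by interferon gamma, 16 rose, none fell and 9 did not pass, with 23 rising when adjusted over the list alone. Irgm1, Ifi47 and Tgtp2, GTPases of the defence against intracellular microbes, rose by 1.07 ± 0.15, 1.39 ± 0.20 and 2.02 ± 0.30, and Tgtp2 can share reads with its near-identical copy. The list's mean was 1.39 with camera adjusted p = 1.35e-11 and adjusted p = 0.364 with an estimated correlation. Aged replicate 4 had the highest mean log2 CPM of this list, 6.18 against a mean of 4.97 in the other aged libraries, and the list's mean log2 fold change was 1.09 without it.

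Genes of presentation by MHC class II also rose, 10 of 16, while Cd40 fell and 5 did not pass; 13 rose and 1 fell when adjusted over the list alone. H2-Ob, H2-DMb2 and H2-Eb2 rose by 1.52 ± 0.14, 1.52 ± 0.15 and 2.64 ± 0.36, and Cd40, a costimulatory receptor, had -0.69 ± 0.11. For the list, with a mean of 0.99, camera gave adjusted p = 1.55e-05, and adjusted p = 0.267 with an estimated correlation. In aged replicate 4 the list's mean log2 CPM was 6.64 against 5.84 in the other aged libraries. B cells, which express these genes as well, had markers that rose by a mean of 1.45 on the log2 scale in the same libraries.

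Inflammatory genes moved unevenly. Of 15 tested cytokines and chemokines, 4 rose, none fell and 11 did not pass, with the same counts when adjusted over the list alone. The chemokine gene Cxcl16 rose by 0.89 ± 0.13 (log2, SE, n = 4 per group) from 28.6 ± 2.6 to 52.95 ± 10.9 CPM (SD), and Ccl2, Ccl5 and the cytokine gene Il27 rose by 3.02 ± 0.46, 2.74 ± 0.41 and 1.30 ± 0.23 at low levels, with group means of Ccl2 and Ccl5 under 2 CPM. Il1b (1.39 ± 0.60), Il6 (0.30 ± 0.43) and Tnf (-0.56 ± 0.39) did not pass, with adjusted p of 0.164, 0.711 and 0.417. Without aged replicate 1, Tnf was lower in aged libraries by more (-1.19, adjusted p = 0.00684), as it was with limma-voom and sample quality weights (-1.196, 0.0101), while Il1b had 0.63 and Il6 -0.15 with adjusted p of 0.414 and 0.820; without aged replicate 3 Tnf had -0.32. The list's mean of 0.59 had camera adjusted p = 0.0185 and adjusted p = 0.445 with an estimated correlation. Without aged replicate 1 its mean was 0.39 with adjusted p = 0.189.

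Of 22 targets of NF-kB, 8 rose, 1 fell and 13 did not pass, with 10 and 1 adjusted over the list alone. Traf1, an adaptor of TNF receptors, rose by 1.71 ± 0.19, Tnip1, an inhibitor of NF-kB signalling, by 0.55 ± 0.11, and the survival genes Bcl2a1d and Bcl2a1b, close copies that can share reads, by 2.17 ± 0.31 and 0.63 ± 0.12. Their list had a mean of 0.38 with camera adjusted p = 0.00249 and adjusted p = 0.372 with an estimated correlation. Of 17 inflammasome genes, 6 rose, 1 fell and 10 did not pass, with 6 and 1 adjusted over the list alone. The caspase genes Casp4 (0.60 ± 0.08) and Casp1 (0.47 ± 0.10), the sensor genes Nlrp3 (0.87 ± 0.20) and Naip1 (0.44 ± 0.09) and Mefv (2.43 ± 0.34) rose. Naip1 has close copies. Mefv was at a low level in young libraries, with a log2 CPM of -1.28 in young replicate 1 and a mean of -0.41 in the others. Nlrp3 had adjusted p of 0.0543 and 0.0534 without young replicate 1 or 3, and 0.0683 with no filter on low counts. Inflammasome genes had a mean of 0.35 with camera adjusted p = 0.0185 and adjusted p = 0.235 with an estimated correlation.

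Of 30 pattern-recognition receptors and adaptors, 7 rose, 3 fell and 20 did not pass, with 8 and 5 adjusted over the list alone, and camera gave adjusted p = 0.370 for a mean of 0.0864. The mean was 0.14 without aged replicate 1 and 0.0466 without aged replicate 4. Irak3, a brake on Toll-like receptor signalling, rose by 0.55 ± 0.08, the lectin gene Clec4n by 1.56 ± 0.27 and the peptidoglycan sensor gene Nod1 by 0.47 ± 0.09, and Tlr1 fell (-0.81 ± 0.14). Of 24 immediate-early genes, 5 rose, 2 fell and 17 did not pass, with 7 and 2 adjusted over the list alone, and camera gave adjusted p = 0.0760 for a mean of 0.46. That list passed without young replicate 1 (0.52, adjusted p = 0.0269), young replicate 3 (0.47, 0.0455) or aged replicate 3 (0.54, 0.0304), and with the members of other lists left out (0.63, 0.00957). Egr1, Fosb and Egr2 rose by 1.05 ± 0.15, 2.07 ± 0.31 and 2.15 ± 0.43, and Myc fell (-0.42 ± 0.07).

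Scavenger and phagocytic receptors went both ways, with 6 of 30 rising, 3 falling and 21 not passing, and 7 and 5 adjusted over the list alone. Stab1 fell, and Scarb2, a lysosomal membrane receptor, Cd300a, a phosphatidylserine receptor, and Fcgr4, an IgG receptor, rose by 0.77 ± 0.07, 0.71 ± 0.10 and 1.28 ± 0.24; Fcgr4 had adjusted p = 0.0504 without aged replicate 1. Mertk, the efferocytosis receptor kinase, had 0.10 ± 0.11 and adjusted p = 0.630, and 0.0363 to 0.17 when 1 library was left out. Camera gave adjusted p = 0.436, and the list's median (0.07) and mean (-0.02) differed in sign. Leaving out 1 library gave means from -0.0396 (young replicate 3) to -0.00131 (aged replicate 2).

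Lysosomal genes rose, 11 of 40, with none falling and 29 not passing; 19 rose and 1 fell adjusted over the list alone. Cd63, a tetraspanin of late endosomes, rose by 1.41 ± 0.17 and the protease genes Ctsl and Ctsd by 0.75 ± 0.10 and 0.51 ± 0.07. Lysosomal genes had a mean of 0.24 with camera adjusted p = 6.93e-07 and adjusted p = 0.235 with an estimated correlation. With the members of other lists left out the mean was 0.16 and passed. Of 30 autophagy genes, 6 rose, 1 fell and 23 did not pass, with 9 and 1 adjusted over the list alone. The cargo receptor gene Sqstm1 rose by 0.45 ± 0.08, Gabarapl1 by 0.37 ± 0.09 and Atg5 by 0.35 ± 0.09, and Tfeb, a transcription factor for lysosomal genes, fell (-0.57 ± 0.10). Gabarapl1 did not pass without young replicate 1, 2 or 4 or aged replicate 4 (adjusted p up to 0.0724), nor Atg5 without any of these or aged replicate 2 (up to 0.102). Camera gave adjusted p = 0.0185 for a mean of 0.11, adjusted p = 0.372 with an estimated correlation, and 0.0713 without young replicate 2.

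Genes of lipid-associated macrophages rose for 7 of 16, fell for 3 and did not pass for 6, with 9 and 4 adjusted over the list alone. Plin2, which coats lipid droplets, rose by 1.48 ± 0.11, from 249 ± 35 to 695 ± 50 CPM (SD), and Gpnmb, a glycoprotein of phagocytes, by 3.11 ± 0.29, whereas Trem2, a lipid receptor that defines such macrophages, fell (-1.35 ± 0.11). The list's mean was 0.39 with camera adjusted p = 0.0326, adjusted p = 0.445 with an estimated correlation, and 0.31 with adjusted p = 0.183 without aged replicate 1; without aged replicate 3 the mean was 0.59. Over the 10 members that no other list holds, the mean was 0.36, close to that of all 16, but the adjusted p was 0.414.

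Of 17 targets of LXR and cholesterol efflux genes, 4 rose, 2 fell and 11 did not pass, with 4 and 3 adjusted over the list alone; camera gave adjusted p = 0.936 in the upward direction, whereas the median (-0.01) and mean (-0.16) were negative. Lpcat3 and Nr1h3, which encodes LXR alpha, rose by 0.57 ± 0.08 and 0.97 ± 0.17, and Apoe fell (-0.57 ± 0.09). Of 24 genes of cholesterol synthesis, Insig1 alone passed (0.53 ± 0.11, higher), 23 did not pass, and camera gave adjusted p = 0.210 for a mean of -0.0966. Insig1 alone also passed when adjusted over the list alone. The cholesterol synthesis mean was -0.18 with adjusted p = 0.0458 without aged replicate 4. It was -0.0194, -0.0452 and -0.0509 without aged replicate 1, aged replicate 2 or young replicate 1, and did not pass. Of 15 prostaglandin genes, 4 rose, 2 fell and 9 did not pass, with 4 and 3 adjusted over the list alone. Ptges and Slco2a1 rose by 0.88 ± 0.13 and 1.73 ± 0.32, while Hpgd (-2.70 ± 0.38) and Ptgs1 (-0.45 ± 0.07) fell; camera gave adjusted p = 0.859, and the median (0.03) and mean (-0.05) differed in sign. The mean was -0.0184, -0.0247 and -0.0920 without aged replicates 1, 2 and 4 in turn, and 0.0306 with genes of at least 1 CPM in 4 libraries.

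Complement genes rose for 5 of 17, fell for 1 and did not pass for 11, with 5 and 3 adjusted over the list alone, and camera gave adjusted p = 0.0604 for a mean of 0.400. The list passed without aged replicate 2 (0.46, adjusted p = 0.0300) or aged replicate 4 (0.39, 0.0309). Besides Cd55, an inhibitor of complement on the cell surface, factor B (Cfb), C3 and C1ra rose by 1.17 ± 0.11, 1.08 ± 0.11 and 0.81 ± 0.10, and C3 went from 873 ± 50 to 1850 ± 314 CPM (SD). Of 15 genes of alternative activation, 2 rose, 3 fell and 10 did not pass, with 3 and 7 adjusted over the list alone, and camera gave adjusted p = 0.115 for a mean of -0.26. This mean was 0.11 with the members of other lists left out (adjusted p = 0.587). Il4ra and Il10 rose by 0.49 ± 0.08 and 2.04 ± 0.42, and Cd163, a haemoglobin scavenger receptor, and Pparg fell (-1.49 ± 0.19 and -1.81 ± 0.35). Il10 was at a low level in young libraries, with a log2 CPM of -1.69 in young replicate 2 and a mean of -0.42 in the others.

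**Figure D4:**
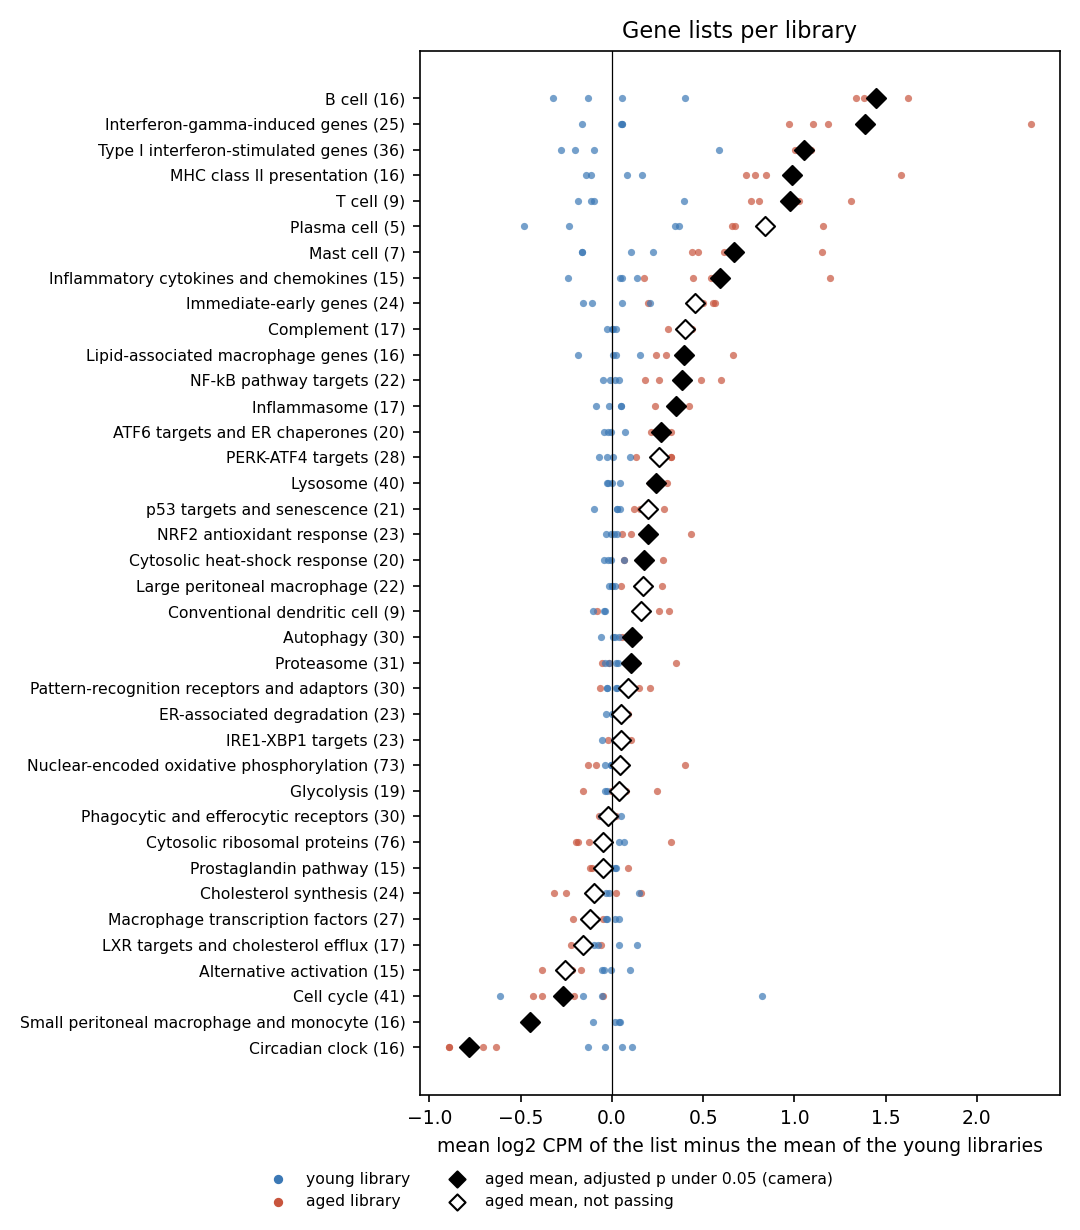
Mean log2 CPM of each of the 38 tested gene lists in each library, minus the mean of the young libraries (x axis, log2 units; the number of tested genes stands beside each list). Small points are libraries (blue, young; red, aged) and diamonds the aged mean, filled for the 19 lists that passed camera with a preset correlation.

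Output and period genes of the circadian clock fell in aged macrophages, and a pair of genes of the opposing limb rose. Of 16 tested members of the circadian list, 10 fell, 2 rose and 4 did not pass, with the same counts adjusted over the list alone. Besides Dbp, Tef, Per2 and Per3, Nr1d2, a nuclear receptor that represses the positive limb, fell (-0.997 ± 0.082), and Nfil3, a repressor of the same targets as Dbp, rose by 1.74 ± 0.10, from 14.9 ± 1.8 to 49.7 ± 4.0 CPM (SD). Arntl, the other gene that rose, encodes the positive-limb factor BMAL1 and was chosen after its values were seen; it rose by 2.01 ± 0.24. The list's mean was -0.78 with camera adjusted p = 6.62e-05, and adjusted p = 0.235 with an estimated correlation. The labels used here give no hour of collection.

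Genes of macrophage identity changed in part. Of 27 macrophage transcription factors, 7 fell, 2 rose and 18 did not pass, with 7 and 3 adjusted over the list alone, and camera gave adjusted p = 0.0785 for a mean of -0.12 (-0.14 with adjusted p = 0.0489 without aged replicate 4, and -0.0506 with the members of other lists left out). Irf8 fell (-0.93 ± 0.14), Klf4 fell (-0.64 ± 0.14) and Tfec rose by 1.20 ± 0.15, while Gata6, the factor of large peritoneal macrophages, had 0.06 ± 0.07 and adjusted p = 0.656. Its value was 0.00742 without aged replicate 3 and 0.0354 without young replicate 1. Klf4 had adjusted p = 0.0566 without aged replicate 1. Cd38, an NAD-consuming enzyme, and Timd4, a phosphatidylserine receptor of resident macrophages, fell (-0.68 ± 0.10 and -0.47 ± 0.09).

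Of 21 targets of p53 and senescence genes, 7 rose, 1 fell and 13 did not pass, with 7 and 3 adjusted over the list alone, and camera gave adjusted p = 0.135. Cdkn2a, which encodes the cell cycle inhibitor p16 and ARF, rose by 1.48 ± 0.23, from 9.97 ± 1.87 to 27.8 ± 9.9 CPM (SD), Plk2 by 0.78 ± 0.11 and the lysosomal galactosidase gene Glb1 by 0.48 ± 0.09, and Sesn1 fell (-0.63 ± 0.08). Cdkn1a, which encodes p21, had 0.25 ± 0.10 and adjusted p = 0.154, and 0.15 without aged replicate 4. None of 41 cell cycle genes passed, over all genes or adjusted over the list alone. Their mean was -0.27 with camera adjusted p = 0.0215 and adjusted p = 0.702 with an estimated correlation, and it was 0.01 with adjusted p = 0.960 without young replicate 2, the young library with the highest mean of the list, and -0.47 without young replicate 3. Without aged replicate 2 or aged replicate 3 the adjusted p was 0.0653 or 0.0929. Hmgb2 (-0.36 ± 0.13), Uhrf1 (-0.86 ± 0.38), Cenpa (0.29 ± 0.13) and Cenpe (-0.55 ± 0.25) had the smallest p values. Hmgb2 passed without aged replicate 1 (-0.49, adjusted p = 0.00764) and Uhrf1 without young replicate 3 (-1.14, 0.0331), and without young replicate 2 Uhrf1 had -0.396 and Cenpe -0.24.

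Of 23 genes of the NRF2 antioxidant response, 5 rose, 1 fell and 17 did not pass, with 6 and 1 adjusted over the list alone. Gsr, which reduces glutathione, rose by 0.83 ± 0.10, Me1 by 1.84 ± 0.28 and the ferritin gene Fth1 by 0.45 ± 0.11, and Mafg fell (-0.53 ± 0.10). The list's mean was 0.20 with camera adjusted p = 0.0240 and adjusted p = 0.532 with an estimated correlation; without aged replicate 1 it was 0.12 with adjusted p = 0.183, and without young replicate 4 the adjusted p was 0.0505. Of 20 genes of the cytosolic heat-shock response, 3 rose (Dnaja1, 0.39 ± 0.09; Hspb1, 1.35 ± 0.32; Hsp90aa1, 0.30 ± 0.09), 1 fell (Hsf1, -0.29 ± 0.07) and 16 did not pass, with 7 and 1 adjusted over the list alone. Camera gave adjusted p = 0.0361 for a mean of 0.18 and adjusted p = 0.442 with an estimated correlation, and without aged replicate 1 adjusted p = 0.183. Leaving out young replicate 1, young replicate 4 or aged replicate 4 gave adjusted p of 0.0577, 0.0711 and 0.0630 for the list, and removing a length trend 0.0681. Without young replicate 1 none of Dnaja1, Hspb1, Hsp90aa1 and Hsf1 passed (adjusted p of 0.0544, 0.0618, 0.159 and 0.0618); Hsp90aa1 passed in 3 of the 8 runs that left out 1 library, Hsf1 in 4, and Fth1 in all but those without young replicate 2 or 4 (0.0589 and 0.0628).

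None of 31 proteasome genes, 73 nuclear genes of oxidative phosphorylation or 76 cytosolic ribosomal protein genes passed edgeR's main test, over all genes or adjusted over the list alone. The proteasome list alone among these passed camera, with a mean of 0.11, adjusted p = 0.0298 and adjusted p = 0.698 with an estimated correlation. Without aged replicate 1 the proteasome mean was 0.03 with adjusted p = 0.559, and without young replicate 1, young replicate 2 or aged replicate 4 the adjusted p was 0.0719, 0.0660 and 0.0630. Without aged replicate 2 the mean was 0.16. Psmd1 had 0.24 ± 0.07, Atp5o 0.31 ± 0.12 and Rps27a 0.84 ± 0.28, with adjusted p of 0.0592, 0.124 and 0.0796. Psmd1 passed without aged replicate 1 (0.0311) and Rps27a without aged replicate 3 (1.08, adjusted p = 0.00229), and Atp5o had 0.17 without aged replicate 1. Rpl18, Rpl27 and Rpl15 passed as lower in aged libraries without aged replicate 1 (-0.298, -0.25 and -0.18, with adjusted p of 0.00391, 0.0135 and 0.0239). Camera gave adjusted p = 0.345 for oxidative phosphorylation, and 0.174 for ribosomal proteins. With an estimated correlation, which was 0.749 and 0.816 for these lists, the adjusted p was 0.905 and 0.880. Camera runs without a library or with the length trend removed used only the preset correlation of 0.01. Their adjusted p can be too small where the genes of a list vary together. Oxidative phosphorylation had a mean of -0.0684 with adjusted p = 0.0117 without aged replicate 1 and of 0.11 with adjusted p = 0.0190 without aged replicate 2, against 0.0469 in all libraries and 0.0888 without aged replicate 3. Ribosomal proteins had a mean of -0.17 with adjusted p = 2.61e-11 without aged replicate 1, and of -0.0601 with adjusted p = 0.0113 with a length trend removed, against -0.0462 in all libraries. Without young replicate 1 or aged replicate 2, 3 or 4 the ribosomal mean lay from -0.0280 to 0.00368 and did not pass. Of 19 glycolysis genes, 2 rose, 2 fell and 15 did not pass, with 6 and 3 adjusted over the list alone, and camera gave adjusted p = 0.174 for a mean of 0.0402. The glycolysis mean was 0.11 with adjusted p = 0.0205 without aged replicate 2 and -0.0278 without aged replicate 4, 0.0245 without young replicate 1 and 0.0129 with genes of at least 1 CPM in 4 libraries. Hk1 and the lactate transporter gene Slc16a3 rose by 0.26 ± 0.07 and 0.62 ± 0.13, and Hk2 fell (-0.91 ± 0.13); Hk1 passed in 2 of the 8 runs that left out 1 library (adjusted p up to 0.111). Gapdh fell too (-1.46 ± 0.26), but was counted at only 25.3 ± 11.4 and 9.19 ± 1.35 CPM (SD), a level far below that of an abundant enzyme. It can share reads with pseudogenes, which was not tested.

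Marker genes of other cell types that the sort could let through were compared between the groups by the mean log2 CPM of each list per library. B cell markers were higher in aged libraries by 1.45 log2 units, at 2.02 ± 0.31 (SD, n = 4) in young and 3.47 ± 0.12 in aged. Of 16 tested B cell genes, 13 rose, none fell and 3 did not pass, with 13 rising adjusted over the list alone. Fcmr, the IgM receptor, rose by 2.34 ± 0.18 (log2, SE), the B lineage factor gene Pax5 by 2.01 ± 0.19, the receptor component gene Cd79b by 1.55 ± 0.15, from 6.85 ± 1.52 to 20.1 ± 1.8 CPM (SD), and the kinase gene Blk by 2.16 ± 0.24. The B cell list had camera adjusted p = 5.77e-13, and adjusted p = 0.235 with an estimated correlation.

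Markers of T cells rose for 5 of 9, fell for 1 and did not pass for 3, with 7 and 1 adjusted over the list alone. Tcf7, Ltb and Lck rose by 2.14 ± 0.29, 1.504 ± 0.23 and 1.63 ± 0.32 and Cd28 fell (-1.59 ± 0.35), with group means under 5 CPM. The T cell list had camera adjusted p = 0.00284, and adjusted p = 0.267 with an estimated correlation; with genes of at least 1 CPM in 4 libraries its mean was 0.59 against 0.98, with adjusted p = 0.116. Of 7 mast cell markers, Mcpt4 and Hdc rose by 1.62 ± 0.39 and 0.65 ± 0.16 and 5 did not pass, with 3 rising adjusted over the list alone. The mast cell list had camera adjusted p = 0.0185, adjusted p = 0.364 with an estimated correlation, and 0.114 without aged replicate 1. Mcpt4 did not pass without young replicate 1, 2 or 4 (adjusted p up to 0.0651), nor Hdc without young replicate 1, 3 or 4 or aged replicate 1 or 3 (up to 0.0762). Of 5 plasma cell markers, Mzb1 (1.46 ± 0.29) and Prdm1 (1.88 ± 0.46) rose and 3 did not pass, with 3 rising adjusted over the list alone, and camera gave adjusted p = 0.0760, and 0.0417 without young replicate 1. Prdm1 did not pass without young replicate 2 or 4 or aged replicate 3 or 4 (adjusted p up to 0.0615). Immunoglobulin genes were not analysed here.

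Markers of small peritoneal macrophages and monocytes fell for 6 of 16, rose for 2 and did not pass for 8, with 8 and 2 adjusted over the list alone. Ccr2, the chemokine receptor of monocytes, fell (-1.73 ± 0.19), from 22.8 ± 2.5 to 6.87 ± 1.98 CPM (SD), as did Lyve1 and Folr2 (-0.85 ± 0.13), while Plac8 rose by 2.64 ± 0.35. Camera gave adjusted p = 0.0185 for a mean of -0.45, adjusted p = 0.235 with an estimated correlation, and 0.119 with the members of other lists left out, where the mean was -0.46. Of 22 markers of large peritoneal macrophages, 6 rose, 1 fell and 15 did not pass, with 7 and 3 adjusted over the list alone, and camera gave adjusted p = 0.0654 for a mean of 0.17. It passed without aged replicate 4 (0.21, adjusted p = 0.0193) and with the members of other lists left out (0.21, 0.0380). Cxcl13, a chemokine for B cells, rose by 1.52 ± 0.22, from 507 ± 69 to 1457 ± 491 CPM (SD), and Serpinb2 by 0.80 ± 0.12. The summed CPM of this list was lower in aged libraries, 65371 against 72574.

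Dendritic cell markers gave 1 rise (Ccr7, 2.68 ± 0.29), 1 fall (Clec9a, -2.10 ± 0.51) and 7 not passing of 9, also adjusted over the list alone, and camera gave adjusted p = 0.930 for a mean of 0.16. The dendritic cell mean was 0.51 with genes of at least 1 CPM in 4 libraries (adjusted p = 0.375) and 0.24 without aged replicate 4. Clec9a had adjusted p of 0.0617 and 0.0509 without young replicate 2 or 4. Fewer than 5 genes were tested for 5 further types, which camera left out. Of 4 neutrophil markers Mmp9 fell (-1.33 ± 0.13) and 3 did not pass, with 2 falling adjusted over the list alone. Of 3 eosinophil markers Il5ra rose (1.91 ± 0.43) and 2 did not pass, with 1 rising adjusted over the list alone, and neither of the platelet markers Itga2b (0.59 ± 0.36) and Gp1ba (-0.13 ± 0.31) passed. Eomes, the tested NK cell marker, was counted 7 times in young and 87 times in aged libraries, and Krt8, the tested mesothelial marker, 12 and 205 times; both rose, also adjusted over the list alone. Krt8 was at 5.33 CPM in aged replicate 3 and at 0.519 to 1.33 CPM in the other aged libraries, and its log2 fold change was 2.64 without aged replicate 3 against 3.84 with it, with adjusted p of 0.0595 and 0.0521 without young replicate 1 or 4. Itga2b had 0.199 without aged replicate 3. No erythroid marker and no mitochondrially encoded gene entered the test.

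By an exact two-sided permutation test of the 70 assignments of 4 against 4, 9 of 12 marker lists differed between the groups. These were the B, plasma, T and NK cell, eosinophil, mast cell, mesothelial and large peritoneal macrophage lists, higher in aged, and the list of small peritoneal macrophages and monocytes, lower. Each had exact p = 0.0286, the smallest that the assignments can give, and adjusted p = 0.0381. Of these, the NK cell and mesothelial lists held 1 tested gene each and the eosinophil list 3. Lists of dendritic cells, neutrophils and platelets did not pass, with adjusted p of 0.274, 0.400 and 0.312 by the same exact test. With summed CPM in place of mean log2 CPM, 8 lists passed the exact test. Neutrophil markers then passed as lower in aged libraries (-96.6 CPM, adjusted p = 0.0429). Mast cell and large peritoneal macrophage markers did not pass by sums (adjusted p of 0.0762 and 0.24). Without aged replicate 1 the B cell difference was 1.49 and that of small peritoneal macrophages and monocytes -0.45, but 0 of 12 lists passed, as too few reached the smallest exact p to pass adjustment (lowest adjusted p = 0.0571). Leaving out another library left 7 or 8 lists passing, always those of B cells, NK cells, mast cells and small peritoneal macrophages and monocytes. Among these runs the large peritoneal macrophage list did not pass without any 1 young library, the eosinophil list without aged replicate 2, 3 or 4, the mesothelial list without young replicate 1 or 4, the T cell list without aged replicate 2 and the plasma cell list without aged replicate 4.

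Of 38 lists tested with camera, 16 were higher and 3 lower in aged libraries at a preset correlation of 0.01. None passed with a correlation estimated from the data, where the smallest adjusted p was 0.235 and 6 lists had an unadjusted p under 0.05; fry called 20 lists and the exact permutation of list means 24, of which 14 and 16 were among the 19. Neither compares a list with other genes. Both added the lists of ER-associated degradation, complement, alternative activation, p53 targets and senescence, large peritoneal macrophages and plasma cells, and the permutation also PERK-ATF4 targets and macrophage transcription factors. Both left out the cell cycle, heat-shock and proteasome lists, and fry also the cytokine and NRF2 lists.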

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

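The tests of the time of day, of the phase of aged mice, of sort purity and of the repeat cluster on chromosome 1 were chosen only after the results were seen. Among the 35 splits of the 8 libraries into 4 and 4, only the real split called genes changed with age, with 1703. The highest of the other splits gave 0. A share of 1 in 35 is the smallest that this design can give. Every other split mixes young and aged libraries, so the age difference widens the spread within its groups and can bring its count to 0. The splits alone therefore cannot exclude chance for the count of genes. For the lists, 2 of 35 splits reached 19 lists, the real split and one that exchanged young replicate 2 with aged replicate 3. That other split still sets mostly young against mostly aged libraries, so it keeps part of the age difference. The share of 2 in 35 therefore cannot decide on chance, which stays not excluded for the count of lists at the preset correlation. Splits with 2 young and 2 aged libraries in each group, where age is balanced, still called 3 to 13 lists, fewer than the 19 of the real split.

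Output genes of the clock fell and Arntl and Nfil3 rose, with a difference of 4.07 log2 units between the mean changes of Arntl and Nfil3 and of Dbp, Tef, Per3 and Nr1d2. Aged mice out of phase with one another would vary more than young mice in these genes, if young mice were in phase. The median ratio of SDs, aged over young, was 1.03, against a median of 1.86 in random lists matched for expression. Aged replicate 1 was kept in both, and its deviation could raise the 1.86. The ratio of 1.03 shows no wider spread of clock genes in aged than in young mice. It cannot tell whether both groups varied in phase. The transcript-length bias of aged replicate 1 is argued against, since 13 clock genes passed without that library and 12 with it. Collection of the groups at different times of day cannot be told apart from age, because no hour of collection is given in the labels and both could move the genes in opposite directions by 4.07. Age itself stays open and untested.

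B cell markers rose, and none of the 16 tested is held by another of the lists. For a lower purity of the sort, 41 markers of the other listed types were pooled. Their median log2 fold change was 0.63 (bootstrap 95% interval over markers 0.38 to 1.04), and the interval holds the bound of 0.82. This cannot decide on purity, since a less pure sort need not raise every type by the same amount. The interval also does not cover the variation between mice. A lower purity therefore stays open. A second list of B cell genes had a median of 1.25 (0.18 to 1.47), with 10 of 18 tested genes rising and 1 falling. The lower end of 0.18 lies under the bound set before this test, so the test cannot decide. More B cells carried through the sort stay possible as an account of the rise. Such B cells cannot be told apart from expression of these genes in the sorted macrophages, since pooled cells do not show which cell held a transcript. How many B cells passed the gate on CD11b and F4/80 was not measured here. Of the abundant markers, Cd79a was at 9.74 ± 2.35 CPM (SD, n = 4) in young and 22.7 ± 2.2 CPM in aged libraries.

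Csprs, LOC100041034, Gm7609 and C130026I21Rik, related copies of which Gm7609 and C130026I21Rik lie on chromosome 1 between 84992690 and 85270566, rose by 3.52, 5.91, 4.85 and 3.99 on the log2 scale; Gm7609 and C130026I21Rik were chosen after their values were seen. Reads moved from one counted copy to another would leave the sum unchanged, but the summed counts with Sp100, Sp110 and Sp140 rose by 1.21 (95% interval 0.93 to 1.501). A share in the interferon response cannot be told apart, with a Spearman rho of -0.14 within groups (exact p = 0.769) over few libraries. A sequence or copy-number difference between the mouse stocks could also give the rise and cannot be told apart from age, as stock may coincide with age group. Within 1 Mb, 2 of 14 tested genes changed by over 2-fold (A530032D15Rik, 1.80, and A530040E14Rik, 1.32), against 590 of 12325 over all tested genes. This count cannot decide, since a focal difference could leave the neighbours unchanged. Age stays open and untested.

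For each named gene and list, the library farthest from the other 3 of its group was compared by its gap to the nearest library as a share of the group's range. Of 466 sets of 4 values, 30 passed the 95% limit, against 23.3 expected by chance. In young replicate 2, Vldlr (a share of 1.00, with all 3 young counts) and Irf7 (0.903) were high and Il27 (0.913), Il10 (0.904) and Cdkn2a (0.945) low. In young replicate 1, Tnip1 (0.881) was high and Mefv (0.862), Ndufs4 (0.900), Folr2 (0.853) and the list of IRE1-XBP1 targets (0.856) low. In young replicate 3, Pax5 (0.909) and the T cell list (0.853) were high and Naip1 (0.849), S100a8 (0.877) and the interferon gamma list (0.969) low. In young replicate 4, the list of p53 targets and senescence was low (0.874). In aged replicate 4, Tgtp2 (0.878), Uhrf1 (0.881), the interferon gamma list (0.837) and the MHC class II list (0.873) were high, and Sesn1 (0.854) and Dnajb9 (0.846) low. In aged replicate 1, Batf3 (0.884), Mmp9 (0.833), Lcn2 (0.951), Atf4 (0.863) and the list of ribosomal proteins (0.865) were high. In aged replicate 3, Itga2b (0.914) and Xbp1 (0.934) were high, and in aged replicate 2 the complement list was low (0.839).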

How the results depend on the processing

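Removal of the length trend was chosen after the data were seen. Of 187 named genes, 136 were called, of which 114 passed in every alternative run for them and 136 never reversed; 22 lost the call in at least 1 alternative. Of 51 not called, 23 passed in at least 1 alternative and 6 reversed in some; 14 passed with sample quality weights, 14 with the length trend removed, 13 without aged replicate 1 and 9 with DESeq2. Among them Tnf had -0.56, with -1.19 (adjusted p = 0.00684) without aged replicate 1 and a range of adjusted p up to 0.636, and Eif2ak3 had 0.18, with 0.26 (0.00775) and a range up to 0.480. The 1703 changed genes became 2154 with DESeq2, 1637 with limma-voom, 1392 with a block for replicate number and 2358 with the length trend removed, of which 1661 were shared. Limma-voom with sample quality weights gave 2568 changed genes and 1018 lower. It reversed Lcn2 (-0.0498), Atf4 (-0.0534), Atf6 (0.00604) and Il6 (-0.11), none of which passed in the main test. The same genes reversed in edgeR without aged replicate 1 (-0.11, -0.0965, 0.0364 and -0.15), where 2732 genes changed. The weight given to each library was not examined. The median log2 fold change of all genes was -0.01 with TMM and -0.03 with total counts alone. With an estimated correlation 0 lists passed camera, and ATF6 targets and ER chaperones, at 0.27, had adjusted p = 0.235, against 4.02e-06 as the lowest over its alternatives; the test's allowance for correlated genes is what changed. PERK-ATF4 targets, at 0.26, passed the exact permutation of list means (adjusted p = 0.0452, from 0.0329 to 0.460 over all alternatives). The prostaglandin list became 0.0306 with genes of at least 1 CPM in 4 libraries, and alternative activation 0.11 with members of other lists left out, with fewer genes tested in each. The summed CPM of large peritoneal macrophage markers differed by -7203 between aged and young, opposite to the mean of logs, as sums follow the most abundant genes. Leaving out 1 library at a time gave 1107 (young replicate 1) to 2732 (aged replicate 1) changed genes and 340 to 1097 lower genes, from the same libraries, and the cause was not tested. Marker lists passing numbered 0 (aged replicate 1) to 8; without aged replicate 1 the B cell difference was 1.49, and the calls ended because too few lists reached the smallest exact p to pass adjustment (adjusted p = 0.0571). Over the same runs, log2 values were -0.11 to 0.59 for Lcn2, -0.35 to 0.0212 for Gp1ba, -0.0965 to 0.0899 for Atf4, -0.18 to 0.0364 for Atf6, -0.0841 to 0.0758 for Dnajb9 and -0.15 to 0.53 for Il6. List means were 0.23 to 0.30 for PERK-ATF4 targets (0.0639 with genes of at least 1 CPM in 4 libraries), -0.0684 to 0.11 for oxidative phosphorylation, -0.0278 to 0.11 for glycolysis, -0.47 to 0.00569 for cell cycle and -0.17 to 0.00368 for ribosomal proteins. Leaving out immunoglobulin, haemoglobin and mitochondrially encoded genes was not run, as it would have removed no tested gene. Library names carry the same numbers in both groups, but the labels state no pairing. Deviations from the group means correlated at -0.04 to 0.06 between libraries of the same replicate number and at -0.13 to 0.09 between others. These values show no pairing but cannot exclude one. With the block 8 named genes lost the call, none gained it, and the complement and immediate-early lists passed camera (adjusted p = 0.0461 for both). In simulated data 53.7% of genes changed by 1.5-fold were recovered, so changes of that size can be missed in this design.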

Other observations

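Angptl4 and Cpt1a rose in aged macrophages besides Pdk4 and Plin2. Angptl4, an inhibitor of lipoprotein lipase, went from 1.67 ± 0.45 to 14.7 ± 5.3 CPM (SD, n = 4), with a log2 fold change of 3.14 ± 0.28 (SE). Cpt1a, which admits fatty acids to mitochondria, went from 192 ± 40 to 378 ± 35 CPM, with 0.98 ± 0.14. Both were chosen after their values were seen.

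The test of the fatty acid list was planned after these 4 genes were seen and before the other members were. As a hypothesis, Pdk4, Angptl4, Cpt1a and Plin2 may belong to a shared rise of fatty acid oxidation and PPAR target genes. In 26 tested genes of such a list without these 4, the median log2 fold change was 0.16, and 7 rose, none fell and 19 did not pass; those that rose include Acadl (0.71 ± 0.13) and Slc25a20 (0.77 ± 0.17). Camera gave p = 0.000508 at the preset correlation and p = 0.236 with an estimated correlation, so the list passed only at the preset correlation. The median and the counts of genes do not depend on that choice, but genes that vary together are not independent of one another. Pparg itself fell (-1.81).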
